A study of Mus musculus and Ochotona curzoniae and Rattus norvegicus with 18 samples.

How the data were processed

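RNA was sequenced from cultured skin fibroblasts of 4 species, the Tibetan pika, the C57BL/6J mouse, the Sprague Dawley rat and the New Zealand White rabbit, with 3 libraries per species and 12 libraries in all. The cells were collected at 90% confluency, per the labels' protocols. The series also lists 6 ChIP-seq samples, which are not analysed here. Their treatment and extract protocols give different lengths of treatment with DMOG, an inhibitor of the enzymes that mark HIF proteins for breakdown.

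Each RNA-seq file held 1 FPKM value per gene, that is, fragments relative to gene length and library total, as the authors deposited it. STAR 2.6.1a, featureCounts, edgeR 3.28.1 and CASAVA 1.9 are listed without an order in the submitters' processing notes. GRCm38, a mouse build, is the only build those notes list for any of the species, although the rows of the deposited FPKM tables carry identifiers that differ between species. The annotation of each species is not given in the sources used here. FPKM divides the reads of a gene by the length of its model, so a species whose gene models are shorter gets higher values from the same number of reads.

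The FPKM values of a gene were whole multiples of a step that depends on the gene's length and the library's total. Whole reads, gene lengths and library totals were worked out from these steps, with a tolerance of 0.002 reads. The totals were 8159478, 7703576 and 8481030 reads for pika, 5758950, 3663102 and 4742265 for mouse, 3306465, 3835272 and 3550722 for rat, and 10287475, 9453123 and 10451198 for rabbit. Of 4000 simulated rows, 3773 were above 0 in at least 2 libraries, and on these 90.5% of reads and lengths were recovered exactly and 97.5% exactly or divided by a shared whole number. The reads recovered added up to between 95.7% and 96.4% of each total, so a gene's reads and length can be too small by a shared factor. The main test therefore does not use reads per gene, which enter the replicate comparison, the gene length bins, some alternatives and the description of depth.

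Replicates were compared on these reads. The mean chi-square per gene lay between 1.35 and 1.52 for the pika pairs, 1.48 and 2.93 for mouse, 1.65 and 3.51 for rat, and 5.07 and 6.73 for rabbit, where sampling alone gives about 1. No pair of libraries was a repeat of the other. Nothing in the labels says that the 3 libraries of a species came from separate animals or cultures, and the p-values then measure only the spread between these libraries, which may be technical.

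Pika rows were named by gene symbol, 3694 of the 19398 rows were numbered LOC names, and 24 had been turned into dates. Mouse identifiers were named with a table of mouse genes, which gave a symbol for 49326 of 49585. A symbol found once in each table joined 14428 genes. Rat and rabbit identifiers are not paired with symbols in the files or in the tables used here. These 2 species were therefore left out of the comparisons, as the design fixed before the data were examined allows, and the fit held 6 libraries instead of the 12 planned. The joined genes held about 87.6% of the pika FPKM and between 37.3% and 38.6% of the mouse FPKM.

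Each library was rescaled so that the joined genes summed to 1000000. Values are given on this scale as rescaled FPKM, as mean ± SD over 3 libraries. Genes with a mean deposited FPKM of 1 or more in at least 1 of the 2 species were tested, 10356 in all, with limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1). The tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of 1 or more. Fold changes are pika over mouse on the log2(value + 1) scale, which understates the change of low genes. Gene lists of at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over 24 lists, and again with an estimated correlation. On data simulated for this comparison with 9373 genes, all 100 genes changed 4-fold and all 100 changed 3-fold were called in the right direction, and 5 of 9173 unchanged genes were called. Both simulated groups were drawn from the mouse read levels with the mouse gene lengths. The simulation therefore held no difference in annotation, gene length or scale, and gives no rate of false calls between species. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

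The 26 gene lists and the rule for named genes were fixed before the data were examined. The text may name every measured core clock and HIF pathway gene. From each other list it may name up to 4 called members with the largest absolute fold change or, where fewer than 2 were called, up to 2 further members with the highest level. Over all genes it may name the 10 higher and 10 lower genes with the largest fold change among those at or above the median level and above 0 in every library. The rule asked for the same direction against all 3 other species, and only mouse could be used. Some genes that the rule names are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

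The alternatives set before the data were examined were median-of-ratios and upper-quartile scaling, FPKM without rescaling, limma without trend, no filter, a filter at 5, a pseudocount of 0.1, no fold minimum, a replicate block, and each library left out. Alternatives chosen after seeing the data were voom on the reads worked out, reads without gene length, removal of the length trend, mouse synonyms, and genes above 0 in all 6 libraries. Positions are those of GRCm38.p6 in a RefSeq table.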

Results

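The series was set up to compare core clock gene expression between the fibroblasts of several species, and to map where Epas1, a hypoxia-inducible transcription factor, binds by ChIP-seq. The ChIP-seq samples, with Bmal, Flag or input in their titles, are not analysed here. The RNA-seq part held 3 libraries each of pika, mouse, rat and rabbit fibroblasts. The Tibetan pika is a small relative of rabbits that lives at high altitude. The totals behind the deposited FPKM ranged from 7703576 to 8481030 reads in pika, 3663102 to 5758950 in mouse, 3306465 to 3835272 in rat and 9453123 to 10451198 in rabbit. Genes at 1 FPKM or more numbered 11220 to 11261 in the pika libraries, 14692 to 14866 in mouse, 12737 to 12765 in rat and 12364 to 12480 in rabbit. The 10 most abundant rows took about 4.3% of the FPKM in pika, 39.1% to 41.0% in mouse, 10.97% to 11.5% in rat and 12.1% to 13.1% in rabbit. Only pika and mouse could be joined gene by gene, and the comparisons below are between these 2 species. Species, genome and gene annotation cannot be separated in this design.

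The first comparison asked how the core clock differs between pika and mouse fibroblasts. Core clock genes differed in both directions. The labels give no time of collection or synchronisation for these cells, so each value is a level at an unknown phase of the clock. NPAS2, a partner of ARNTL that can stand in for CLOCK, was at 52.9 ± 3.45 in pika and 1.98 ± 1.07 in mouse (SD, n = 3), a log2 fold change of 4.23 (SE 0.22). BHLHE41, a repressor of CLOCK and ARNTL activity, was at 140.3 ± 12.0 in pika and 1.83 ± 0.354 in mouse, with a log2 fold change of 5.65. The PAR-domain factor HLF (log2 fold change 3.01) and the repressor CRY1, at 34.3 ± 1.79 in pika and 11.5 ± 0.546 in mouse, were the other genes called higher. Lower in pika were NR1D1 (log2 fold change -2.77) and NR1D2 (-1.59), nuclear receptors that repress ARNTL, and also PER2 (-2.70), NFIL3 (-2.19), CRY2 (-1.44) and DBP (-1.18).

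Of 21 core clock genes, 19 were in both tables and 17 were tested. By limma-trend 4 were called higher, 6 lower and 7 were not called, and the counts adjusted over the list alone were also 4 and 6. Of all 10356 tested genes 52.2% were called. Calls in both directions therefore do not by themselves set apart this list or the clock modifier and HIF lists below. ARNTL, also named BMAL1, was at 29.9 ± 3.21 in pika and 17.0 ± 2.82 in mouse, a log2 fold change of 0.79 (limma-trend adjusted p = 0.00034) that stayed under the fold minimum. CIART (0.73), BHLHE40 (0.31), PER1 (-0.25) and TEF (-0.31) also had an adjusted p under 0.05 and a log2 fold change inside the minimum. CLOCK, at 29.0 ± 1.16 and 31.5 ± 0.430, did not differ by this test (adjusted p = 0.16 by limma-trend), nor did RORA, at 36.6 ± 3.62 and 36.9 ± 1.33 (adjusted p = 0.85 by limma-trend). RORB was listed at 0 in every pika library and was not tested. The list as a whole did not stand apart from other genes (camera adjusted p = 0.64), and its median log2 fold change of -0.12 and mean of 0.22 differed in sign. In mouse GRCm38, Npas2 lies on chromosome 1 from 39193702 to 39363240, Bhlhe41 on chromosome 6 from 145858243 to 145865420, Nr1d1 on chromosome 11 from 98767932 to 98775377 and Per2 on chromosome 1 from 91415977 to 91459351.

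The low level of PER2 in pika rested on few reads, 7 over the 3 libraries against 105 in mouse. The low mouse levels of NPAS2, HLF and BHLHE41 likewise rested on 13, 14 and 34 reads. Without division by gene length, the log2 fold changes of CLOCK (-1.34), RORA (-2.14) and TEF (-2.37) passed the fold minimum. BHLHE40 (-0.56) and PER1 (0.29) changed sign. The pika and mouse models had 2856 and 13727 bases for CLOCK, 1431 and 13071 for RORA, and 869 and 7865 for TEF. A shorter model can also collect fewer reads, so undivided reads depend on model length too, here and in the lists below. Without rescaling, 9 core clock genes were called higher and 2 lower, and NR1D2, NFIL3, CRY2 and DBP were no longer called.

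**Figure D1:**
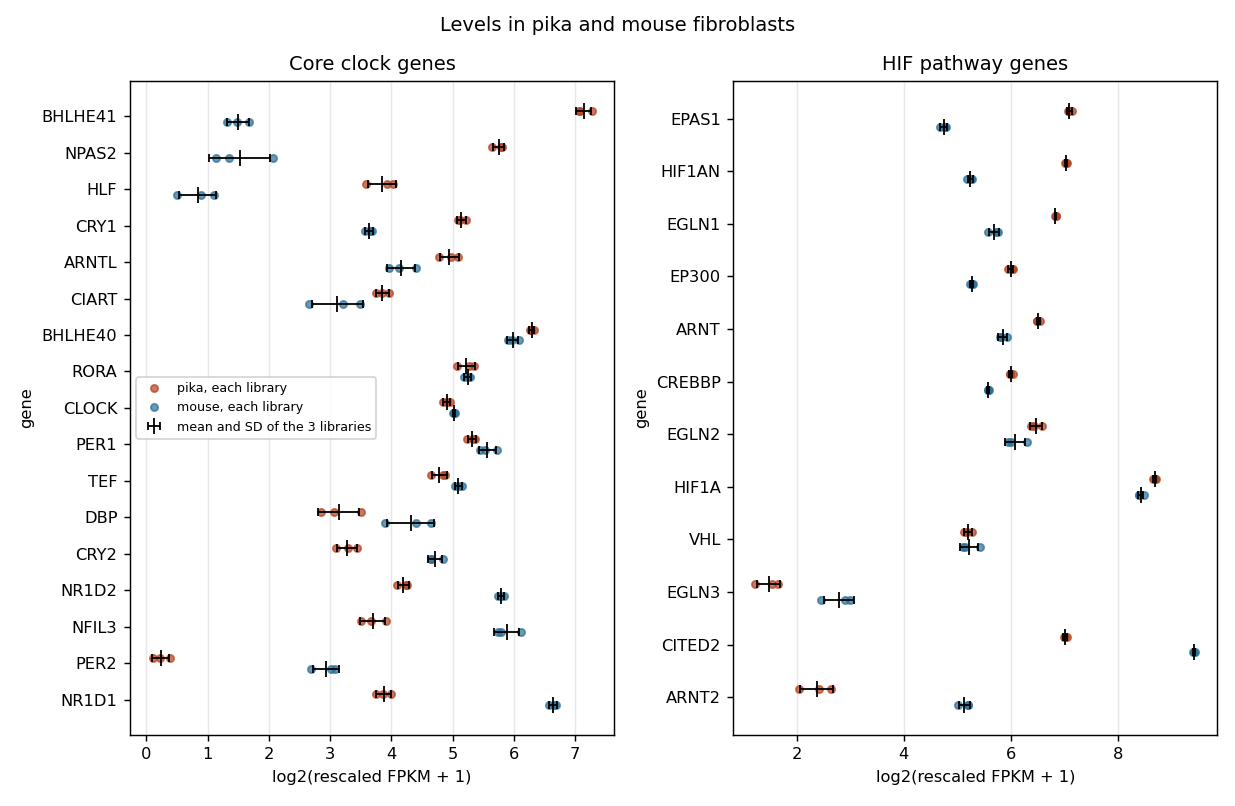
Levels of the tested core clock genes (left) and HIF pathway genes (right) on the x axis as log2(rescaled FPKM + 1), with 1 point per library and bars for the mean and SD of 3 libraries. BHLHE41 and NPAS2 lie far to the right in pika, with log2 fold changes of 5.65 and 4.23, and NR1D1 lies to the left, at -2.77.

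Genes that modify clock proteins were measured next. Of 18 tested, 7 were called higher, 2 lower and 9 not called, with the same counts adjusted over the list alone. TIMELESS, which also acts at replication forks, was at 53.6 ± 1.09 in pika and 5.36 ± 1.33 in mouse (log2 fold change 3.12). The kinase subunit PRKAA2 (3.04), the RNA-binding protein HNRNPD (2.54) and the deacetylase SIRT1 (2.31) were also higher. The list did not pass the set test (camera adjusted p = 0.14).

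EPAS1, whose binding sites the series set out to map, was higher in pika, at 135.1 ± 3.85 against 25.7 ± 1.16 (SD, n = 3), a 5.09-fold difference (log2 fold change 2.35, SE 0.06). The mouse gene lies on chromosome 17 from 86753864 to 86833410. HIF1A was close in both species, at 409.3 ± 7.18 and 341.2 ± 11.9, with a log2 fold change of 0.26. HIF1AN, which blocks HIF activity by hydroxylation (log2 fold change 1.79), and EGLN1, the main oxygen-sensing hydroxylase (1.14), were higher in pika. CITED2, which competes with HIF for its coactivator (-2.40), ARNT2 (-2.76) and EGLN3 (-1.31) were lower.

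Of 12 HIF pathway genes tested by limma-trend, 3 were called higher, 3 lower and 6 not called, with the same counts adjusted over the list alone. The uncalled genes were HIF1A, ARNT (0.66), EP300 (0.73), CREBBP (0.42), EGLN2 (0.38) and VHL (-0.03). HIF3A and CITED4 were too low to test. The list did not pass the set test (camera adjusted p = 0.44). EGLN1 fell under the fold minimum with 2 other scalings, and without gene length HIF1AN (0.56), CITED2 (-0.38) and EGLN3 (-0.78) did so. Without gene length CREBBP was called higher (1.60) and VHL lower (-2.31). EGLN3 also lost its call without rescaling (-0.21), where all 6 uncalled genes were called higher.

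Genes known to respond to HIF differed in both directions. Of 32 tested, 8 were called higher, 10 lower and 14 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.87). NDRG1 (log2 fold change 3.15) and STC2 (3.81) were higher in pika. ADM, which encodes the vasodilating peptide adrenomedullin, was at 2.16 ± 1.14 in pika and 692.8 ± 17.1 in mouse (-7.85). EPO, the hormone that drives red cell production, was listed at 0 in each pika library and was at 65.0 ± 4.96 in mouse. The median of this list was 0.07 and its mean -0.36.

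Of 15 glycolysis genes tested, 5 were called higher, 1 lower and 9 not called, the same as adjusted over the list alone. LDHB, the heart-type lactate dehydrogenase subunit, was at 645.6 ± 5.20 in pika and 94.9 ± 7.80 in mouse (log2 fold change 2.76), with PFKP (2.43) and ENO1 (1.48) also higher and HK2 (-1.68) lower. The set test was not passed (camera adjusted p = 0.17). Among nuclear genes of oxidative phosphorylation, 7 of 17 were called higher, 1 lower and 9 not called, also adjusted over the list alone, and the list was higher as a set (camera adjusted p = 0.026; adjusted p = 0.17 with an estimated correlation). NDUFB8 (2.21), NDUFB5 (1.91) and SDHB (1.46), subunits of complexes at the start of the respiratory chain, and NDUFA4 (1.27) led it. This set call was lost with limma without trend and with the filter at 5. Without gene length NDUFB5 (0.99), NDUFA4 (0.88) and ENO1 (0.80) fell under the fold minimum, as HK2 (-0.40) did without rescaling.

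**Figure D2:**
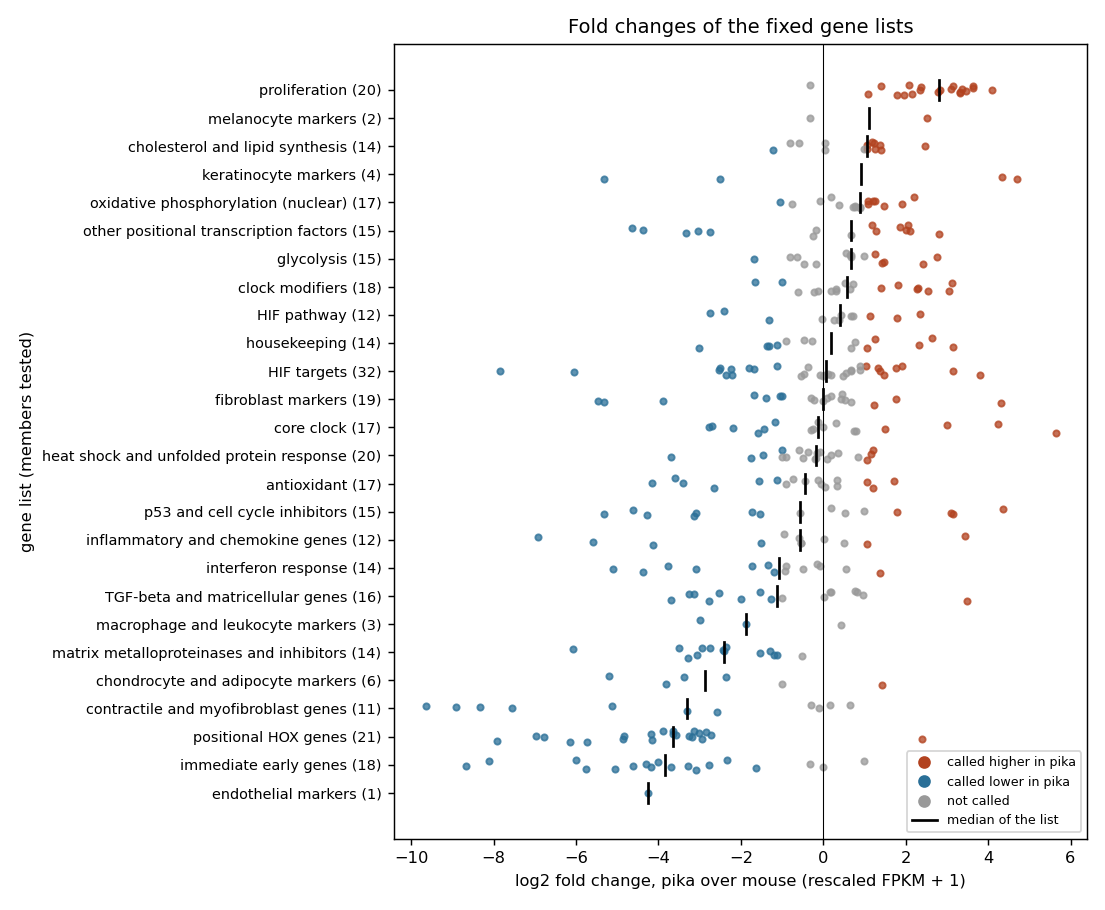
Log2 fold change of pika over mouse (x axis) for the tested members of each fixed gene list (y axis), with 1 point per gene and a black line at the list's median. Proliferation genes lie on the right with a median of 2.81, and HOX genes and immediate early genes lie on the left.

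Over all tested genes, 2976 were called higher in pika and 2427 lower, together 52.2% of 10356. An adjusted p under 0.05 without a fold minimum was reached by 9178 genes. Of the 24 gene lists tested as sets, 6 passed with the preset correlation and 0 with an estimated one. The median log2 fold change over all genes was 0.21, and without rescaling it was 1.29, which gave 6035 genes higher and 1107 lower. Higher calls made up 55.1% of calls with the shared-gene total as the scale, 48.9% with median-of-ratios scaling and 84.5% without rescaling. The counts given for single lists also hold for the shared-gene scale and can move with it, so the counts alone do not fix a direction. Those of the core clock went from 4 higher and 6 lower to 9 and 2 without rescaling. Set against the median of all genes, list medians kept their sign across the scalings and without rescaling, except for fibroblast markers and reference genes. The most strongly higher of the abundant genes were CLU, which encodes the chaperone clusterin (log2 fold change 7.69), DSCC1 (6.09), TENM3 (5.91), PALMD (5.86), GSTM3 (5.78), BHLHE41, FAM180A (5.55), DTL (5.49), FLT1 (5.41) and RAVER2 (5.20). CLU stood at 1445 ± 24.4 in pika and 6.14 ± 1.72 in mouse. The most strongly lower were FBLN2 (-10.52), ACTG2, ACTA2 (-8.92), EPB41L3 (-8.84), PDPN (-8.53), MFAP5 (-8.35), CNN1 (-8.34), GSN (-8.32), PARM1 (-8.17) and EGR2 (-8.11). FBLN2, an extracellular matrix protein, was at 1630 ± 18.3 in mouse and 0.109 ± 0.0709 in pika. Several of these low levels rested on few reads over 3 libraries. In pika there were 3 for ACTG2, 4 for MFAP5 and 5 for FBLN2, but 298 for ACTA2. In mouse there were 8 for FAM180A and 11 for DSCC1, but 56 for CLU. The order of the genes and the size of their folds are therefore not exact.

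The fraction of higher calls moved with gene length. Mouse gene models were longer than pika models by a median factor of 2.25. Among 1276 tested genes with nearly equal lengths (a ratio between 4/5 and 5/4), 209 were called higher and 392 lower, and among 463 genes at least 8-fold longer in mouse, 210 were called higher and 61 lower.

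**Figure D3:**
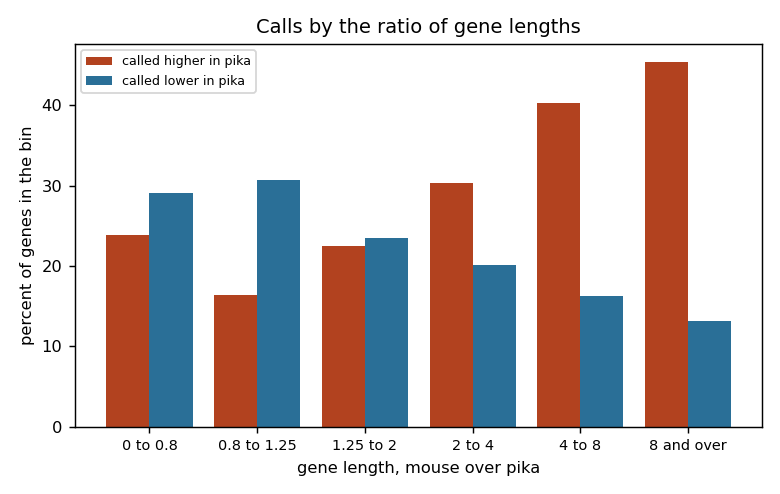
Percent of tested genes called higher (red) or lower (blue) in pika, on the y axis, in bins of the ratio of gene lengths, mouse over pika, on the x axis. The higher calls outnumber the lower ones from a ratio of 2 upward, with 1127 against 750 genes between 2 and 4.

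Proliferation genes were higher in pika. Of 20 tested, 19 were called higher and 1 was not called, with the same counts adjusted over the list alone, and the median log2 fold change was 2.81 (camera adjusted p = 1.0e-05; adjusted p = 0.13 with an estimated correlation). MCM2 and MCM6, subunits of the helicase that opens DNA for replication, were at 300.8 ± 3.64 and 384.9 ± 6.78 in pika and 16.8 ± 0.963 and 33.9 ± 2.40 in mouse. TYMS (log2 fold change 3.64) and AURKB (3.64), which act in nucleotide synthesis and chromosome segregation, were also higher. RRM2, named after its value was seen, was the exception, at -0.33.

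Genes of the p53 response and of cell cycle arrest were split, with 4 of 15 called higher, 7 lower and 4 not called, the same adjusted over the list alone (camera adjusted p = 0.52). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, was at 43.5 ± 4.33 in pika and 1097 ± 19.6 in mouse (log2 fold change -4.63), and the p53 target CCNG1 was also lower (-4.29). IGFBP3 was at 52.6 ± 5.31 in mouse and above 0 in a single pika library. CDKN2C, an inhibitor of CDK4 and CDK6, was higher (4.37).

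Contractile genes were lower in pika. Of 11 tested, 7 were called lower, none higher and 4 were not called, also adjusted over the list alone, and the list was lower as a set (camera adjusted p = 0.0060; adjusted p = 0.13 with an estimated correlation). ACTA2, the smooth muscle actin of myofibroblasts, was at 18.8 ± 2.16 in pika and 9556 ± 141.5 in mouse. CNN1 (log2 fold change -8.34) and TPM2 (-7.56), which bind actin filaments, were lower too, and ACTG2 was at 0.200 ± 0.00937 in pika and 962.9 ± 27.3 in mouse. TAGLN, named after its value was seen, was not called (0.16), at 4095 in pika and 3661 in mouse. Actins and tropomyosins are families of similar sequence whose reads can be split between members.

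Genes of TGF-beta signalling and matricellular proteins were called lower in 8 of 16, higher in 1 and not called in 7, with the same counts adjusted over the list alone. LTBP2 (-3.70), SMAD3 (-3.27) and TGFB3 (-3.13) were lower and TGFB2 was higher, at 288.5 ± 14.9 against 25.0 ± 0.743 (log2 fold change 3.48). The set test was not passed (camera adjusted p = 0.10), although it was with voom on reads (adjusted p = 0.018; 0.36 with an estimated correlation) and without rescaling (adjusted p = 0.019; 0.37 with an estimated correlation). Matrix metalloproteinases and their inhibitors were lower in pika in 13 of 14 tested, with none higher, also adjusted over the list alone (camera adjusted p = 3.5e-06; adjusted p = 0.096 with an estimated correlation). ADAMTS5, which cleaves aggrecan, was at 6.55 ± 0.612 in pika and 505.8 ± 4.50 in mouse (-6.07), and MMP2 (-3.51), MMP13 (-3.27) and MMP11 (-3.07) were lower as well.

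Of 19 fibroblast markers tested, 3 were called higher, 7 lower and 9 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.41). COL3A1 was at 22.8 ± 1.43 in pika and 947.5 ± 16.1 in mouse (log2 fold change -5.32). POSTN (-5.47) and the receptor PDGFRA (-3.88) were also lower, and FAP, a surface protease of activated fibroblasts, was higher (4.30). The list's median, set against that of all genes, lay below 0 except without rescaling (0.0019) and with no filter on low values (0.071). COL1A1, named after its value was seen, was not called, with 4761 in pika and 4774 in mouse.

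Markers of other cell types were mostly low in both species. Of 15 keratinocyte markers in both tables, 4 were tested, of which PERP (4.33) and PKP1 were called higher and DSP (-5.31) and SFN lower, the same adjusted over the list alone (camera adjusted p = 0.87). PKP1 was at 26.6 ± 1.14 in pika and above 0 in a single mouse library, and SFN was at 1.05 ± 0.0490 in pika and 10.7 ± 1.54 in mouse. The melanosome protein gene PMEL was higher in pika (2.52), and MITF was not called (-0.32), so 1 of 2 tested melanocyte markers was called. The only endothelial marker tested, TEK, was lower (-4.25). EMCN and PECAM1, with the next highest levels of that list, were too low to test. Among 3 tested macrophage and leukocyte markers, CSF1R (-2.98) and CD68 (-1.88) were lower (camera adjusted p = 0.41). Chondrocyte and adipocyte markers were lower in 4 of 6 tested and higher in 1, with SOX9 (-3.37) and PPARG (-2.35) lower and CEBPA listed at 0 in pika and at 36.0 ± 1.87 in mouse (camera adjusted p = 0.10, and without rescaling adjusted p = 0.0072, or 0.16 with an estimated correlation). CD68 lost its call without rescaling and without gene length, and PPARG without rescaling. In these lists the counts adjusted over the list alone did not differ.

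HOX genes, which keep a record of body position in skin fibroblasts, separated the species. Of 38 in both tables, 20 had a mean of 1 FPKM or more in mouse and 1 did so in pika. By limma-trend 20 of 21 tested were called lower and 1 higher, also adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.096 with an estimated correlation). HOXB13 was at 242.6 ± 4.74 in mouse, HOXC12 at 108.9 ± 17.5 and HOXC13 at 70.3 ± 6.30, and each was listed at 0 in every pika library. HOXB9, at 146.7 ± 15.3 in mouse, was above 0 in a single pika library. HOXA2, named after its value was seen, was the gene called higher in pika, at 15.3 against 2.19 (log2 fold change 2.41). Of the 21, 14 were listed at 0 in all pika libraries, so no fold is given for them. With voom on reads, without gene length, with the length trend removed and among genes above 0 in all libraries, HOXA2 was the only HOX gene tested, so the lower calls could not be checked there.

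**Figure D4:**
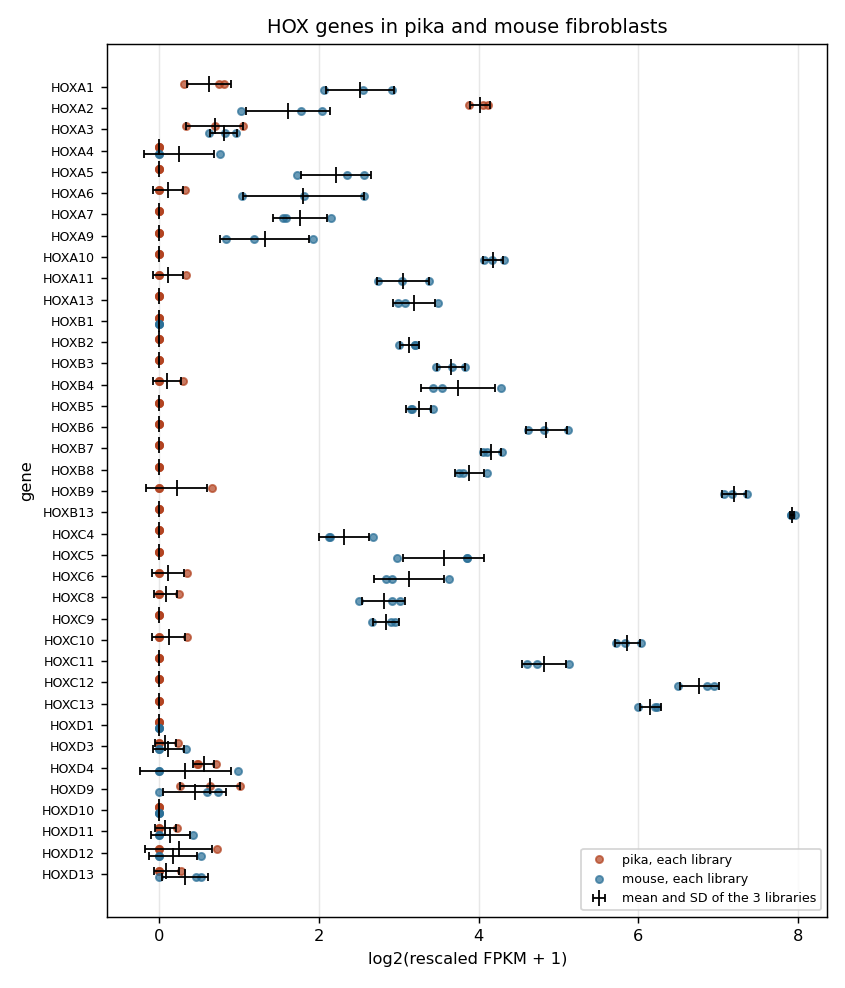
Levels of the HOX genes found in both tables (y axis) as log2(rescaled FPKM + 1) on the x axis, with 1 point per library and bars for the mean and SD of 3 libraries. Of the 12 genes of paralog groups 10 to 13, 8 had a mean of 1 FPKM or more in mouse and 0 in pika.

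Other transcription factors of body position were mixed, with 7 of 15 called higher, 5 lower and 3 not called, the same adjusted over the list alone. EN1 was listed at 0 in pika and was at 24.3 ± 4.68 in mouse, and FOXC2 was lower (-3.04). The median of the list was 0.68 and its mean -0.31, and the set test was not passed (camera adjusted p = 0.89).

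Genes of the antioxidant response were called lower in 6 of 17, higher in 3 and not called in 8, also adjusted over the list alone (camera adjusted p = 0.11, and with the filter at 5 adjusted p = 0.039, or 0.20 with an estimated correlation). HMOX1, which degrades heme, was at 43.3 ± 4.66 in pika and 791.5 ± 12.4 in mouse (log2 fold change -4.17), and the NRF2 targets NQO1 (-3.61), SRXN1 (-3.41) and TXNRD1 (-2.64) were lower too. On the shared-gene scale heat shock and unfolded protein response genes were mostly not called, with 3 of 20 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.22). ATF3 (-3.70), DNAJB1 (-1.76) and HSPB1 (-1.46) were lower and HSPH1 (1.20) higher. DNAJB1 lost its call without rescaling, HSPB1 there and without gene length, and HSPH1 with upper-quartile scaling. Of 14 genes of cholesterol and lipid synthesis, 8 were called higher, 1 lower and 5 not called, also adjusted over the list alone (camera adjusted p = 0.17). ACACA, which makes malonyl-CoA for fatty acid synthesis, was at 144.9 ± 3.64 in pika and 25.4 ± 2.09 in mouse (2.47), and FASN was higher (1.26). LSS (1.41) was higher with gene length divided out and stood at -0.081 without it and at 0.99, under the fold minimum, with the length trend removed.

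Genes often used as references were not level between the species. Of 14 tested, 5 were called higher, 4 lower and 5 not called, the same adjusted over the list alone (camera adjusted p = 0.87). PPIA was at 5168 ± 6.94 in pika and 585.7 ± 24.5 in mouse (log2 fold change 3.14), TBP was higher (2.64) and HPRT1 lower (-3.03), and without gene length TBP stood at 0.71 and was not called. Against the median of all genes this list's median lay just below 0, and at 0.20 without rescaling, 0.27 with no filter and 0.23 without gene length. PPIA and other reference genes have many pseudogene copies, which can take up or add reads.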

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

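The most abundant rows outside the comparison had signal far above 0 in every library of their species, in data that the comparison of pika and mouse did not use. In pika this was LOC101518559, a row without a gene name, at 3391 ± 52.4 FPKM (SD, n = 3). In mouse it was Gm23935, at 121338 ± 3264 FPKM, a row of 57 bases that held 0.68% to 0.71% of the reads, so that its FPKM is set by its short length. The mouse rows Gm42418, AY036118 and CT010467.1 together held 9.39%, 8.02% and 6.93% of the reads in the 3 libraries. In rat it was ENSRNOG00000032882, at 9061 ± 808.9 FPKM with a length of 69 bases. In rabbit it was ENSOCUG00000029097, at 12515 ± 1155 FPKM, also with a length of 69 bases. No control samples exist for these values, and the files do not pair the rat and rabbit identifiers with gene names.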

How the results depend on the processing

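Voom on reads, reads without length, the length trend, synonyms and the restriction to genes above 0 were tried only after the data had been seen. Without rescaling, which shifts the median of all log2 fold changes by 1.07, 6035 genes were higher and 1107 lower, and 9 core clock genes were higher and 2 lower. In that setting the joined genes keep their unequal shares of the FPKM, about 87.6% in pika and 37.3% to 38.6% in mouse. Rows outside the comparison, such as the short mouse row Gm23935, therefore enter the scale. With no fold minimum 5130 genes were higher and 4048 lower, and 7 core clock genes were higher. The filter at 5 tests fewer genes and gave 1578 lower, with 3 core clock genes lower. With an estimated correlation 0 lists passed, against 6. The estimate lay under the preset 0.01 for matrix metalloproteinases (-0.051), contractile genes (-0.037) and oxidative phosphorylation (-0.015). A stronger correlation between genes therefore does not account for the loss of those calls. The estimate lay above 0.01 for HOX genes (0.024), immediate early genes (0.039) and proliferation genes (0.063). HOX genes and matrix metalloproteinases, on either side of 0.01, both went to a camera adjusted p of 0.096. The loss in the lists above 0.01 is therefore not assigned to correlation either. Lists not among the 6 passed without rescaling (interferon response, TGF-beta, chondrocyte and adipocyte), with voom on reads (TGF-beta), without gene length and with the length trend removed (interferon response), and with the filter at 5 (antioxidant), none of them with an estimated correlation. The signs of CLOCK (1.05), RORA (1.16), VHL (1.15) and DBP (0.012) turned without rescaling, by the size of that shift, and LSS turned to -0.081 without gene length. Genes not called in either setting also turned, BHLHE40 (-0.56), PER1 (0.29), MITF (0.50) and ARNT (-0.086) without gene length, PER1 (0.96), TEF (0.87) and MITF (0.90) without rescaling, and RORA and VHL with single libraries left out. Of the 119 called among 133 named genes tested, 100 kept their call in every setting that tested them, 9 besides DBP lost it without rescaling, 9 besides LSS without gene length, 2 with upper-quartile scaling, 1 with median-of-ratios scaling and 1 with the length trend removed. Without gene length 65.6% of the 2832 higher and 81.7% of the 2170 lower calls that could be tested there were kept, and without rescaling 45.6% of the lower calls were.

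Leaving out 1 library gave 2946 to 2992 genes higher and 2415 to 2441 lower, and 4 core clock genes higher, 6 lower and 6 lists in each case. The libraries numbered alike in pika and mouse did not deviate together (correlations across genes of -0.01, 0.05 and 0.01), so no pairing by number was visible in the expression values. Of the 3 pika libraries, 1 correlated best with the mouse library of its own number. With the replicate block 2978 genes were higher and 2427 lower, with 4 and 6 core clock genes and 6 lists. The 6 libraries alone, and symbols matched between the 2 species, were the design itself here. Comparisons with rat and rabbit, and leaving out their libraries, were not run. Mouse had the fewest reads of the 2 species, from 3663102, which limits genes near 1 FPKM.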

Other observations

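Immediate early genes, which serum and stress induce within minutes, were lower in pika. Of 18 tested by limma-trend, 15 were called lower, none higher and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.096 with an estimated correlation). FOS was at 12.5 ± 0.783 in pika and 868.8 ± 9.90 in mouse (SD, n = 3), with a log2 fold change of -6.01, FOSB was at -5.77 and EGR2 at -8.11 on the same scale. EGR3 was listed at 0 in every pika library and was at 406.7 ± 21.3 in mouse.

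Interferon response genes were called lower in 7 of 14 tested, higher in 1 and not called in 6, also adjusted over the list alone (camera adjusted p = 0.074). The set test was passed without rescaling (camera adjusted p = 0.015), without gene length (adjusted p = 0.036) and with the length trend removed (adjusted p = 0.038), but in none of these with an estimated correlation (adjusted p of 0.53, 0.71 and 0.59). IFIT3, at 1.51 ± 0.308 in pika, varied between the mouse libraries, at 90.2 ± 39.1, and IFIT2 (-4.37), BST2 (-3.78) and DDX58 (-3.09), an RNA sensor, were lower. Inflammatory and chemokine genes were called higher in 2 of 12 tested, lower in 4 and not called in 6, with the same counts adjusted over the list alone (camera adjusted p = 0.14). IL6 was higher in pika, at 35.1 ± 1.08 against 2.40 ± 0.768 (log2 fold change 3.44). PTGS2, the inducible cyclooxygenase, was lower (-4.13), CXCL12 was at 0.997 ± 0.0467 in pika and 95.1 ± 9.16 in mouse, and VCAM1, at 130.7 ± 4.10 in mouse, was above 0 in a single pika library.

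Of the tests below, the random lists for the HOX genes were set out before their result was seen, and the others after. HOX genes were called lower in pika in 20 of 21 tested. Random loss of signal in the pika table was tested with 10000 random lists matched on the mouse level. Of these 0% held as many lower calls and the highest held 14, and 1.43% of all tested genes were listed at 0 in every pika library. That argues against random loss of signal among genes with a pika row, the only genes tested. Of 39 HOX genes 38 had a row in both tables, 22 of them at 0 in every pika library, so whole clusters were not missing from the pika annotation. Faulty gene models or alignment across HOX clusters were not tested. A candidate explanation is that the fibroblasts came from different body regions, since 8 of 12 genes of paralog groups 10 to 13 reached 1 FPKM in mouse and 0 in pika. The labels name epidermis for both species and no region, so body region, species and annotation cannot be told apart.

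Proliferation genes were higher in pika in 19 of 20 tested. The median log2 fold change of the list was 2.89 with the gene length trend removed and 2.58 with upper-quartile scaling. Upper-quartile scaling moved the median of all genes by only -0.22, and the removed trend had a slope of -0.30 on the log2 length ratio. Both steps were too small to bring the list under the fold minimum, so they cannot decide about gene models or scale. Without gene length the list was still higher than other genes (camera adjusted p = 1.1e-05; adjusted p = 0.12 with an estimated correlation). Faster growth of the pika cells may be a hypothesis, and species, culture history and growth state stay open as untested.

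Higher calls outnumbered lower calls over all genes. Among genes of nearly equal length 34.8% of calls were higher, and with median-of-ratios scaling 48.9% were. Shorter pika gene models and the choice of scale could therefore each contribute to the excess. It also moved with the filter on low values, from 50.2% of calls with no filter to 62.1% with the filter at 5. The filter was set on deposited FPKM, which rescaling multiplied by 2.14 to 2.15 in pika and by 5.21 to 5.33 in mouse. The filter thus did not act alike on the 2 species. Removing the length trend, which was centred on the median ratio and so leaves the overall shift, left 56.5% of calls higher. None of these results shows which of the 2 scales is right, and no biological explanation was tested.

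The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with as many calls for genes higher (2976, highest other 0), genes lower (2427, highest other 0), core clock genes higher (4, highest other 0) and core clock genes lower (6, highest other 0). For the set tests 6 of the 10 splits gave as many lists, with 6 in the real split and 7 in the highest other. Every other split put libraries of both species into each group. Part of the species difference then stayed between the groups, and part added to the spread within them. The results of those splits are therefore not a chance level, and no conclusion is drawn from them.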
